A study of Mus musculus with 6 samples.

How the data were processed

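The series holds 6 arrays of mouse Lhx2 cells, 3 untreated and 3 treated with TGF-β1 at 10 ng/ml for 2 h, and the labels give each sample's group and replicate number. Total RNA was labelled with Cy3 and hybridised to Agilent arrays of design 014868, annotated on mouse build mm8, and spot intensity was extracted with Agilent Feature Extraction 10.1.1.1, per the file headers. The processed intensity in the authors' scanner files is background-subtracted and spatially detrended within the array and is not scaled between arrays, per the file headers. The authors' series matrix holds log2 values of the same arrays. Set against the scanner files, its columns follow the log2 median spot signal (r between 0.99951 and 0.99989), with medians between 7.383 and 7.417. Whether they were quantile normalized without background subtraction was not tested. The submitters' processing notes name limma, and the version and steps are not given in the sources used here. The matrix had 12 empty rows.

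Each array carried 43379 non-control spots of 41174 probes. The main values were log2 of the processed signal minus the array's 75th percentile of that signal over non-control spots. Spots of one probe were averaged without spots flagged as outliers (43 to 101 per array), and 0 spots were saturated. A probe entered if it was well above background on at least 3 of the 6 arrays, which 36343 did. The files carry no gene symbols, so probes were named through the unversioned RefSeq accession in the systematic name with the reference table of assembly GRCm38.p6, used for names only and for no coordinates. This named 23366 probes (16531 symbols) and left 17808 under the file's own identifier; the latter were tested but are not named in the text. A gene was represented by its passing probe with the highest mean over all 6 arrays. All 10 further probes of the changed genes named by the rule below (8 genes) had the same direction as the probe used, but dimmer probes gave smaller changes for Ldlrad4 (1.45 against 4.07, adjusted p = 0.483) and Calcrl (-0.45 against -1.49, adjusted p = 1). With the mean of its probes Calcrl had -0.97 and was not called (adjusted p = 0.267). A probe not well above background on any array of a group gives only a bound there: the mean of the brighter group against the dimmer group's mean of, per array, the lowest signal among probes well above background or the probe's own if that was higher.

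Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 scale, no covariate), with Benjamini-Hochberg adjustment over 29161 genes and transcripts and a threshold of 0.05. Standard errors are moderated, and n is 3 arrays per group. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 24 lists with at least 4 measured members, with an estimated correlation as the check; camera compares a list with all other genes, and fry, run as an alternative, tests whether a list moves one way. Of 403 list genes 381 were measured. The test of each result, the lists and the rule for naming genes were fixed before the data were examined. The rule takes up to 10 rises and up to 10 falls of greatest size among genes past the threshold with a symbol and non-overlapping groups, then Smad4, Gata2 and Cdkn1c always, up to 4 members past the threshold and up to 2 well-known others from each response list, and the brightest member of each marker list. The well-known members not past the threshold were not listed gene by gene beforehand and were picked with their values in view. Genes named outside the rule, chosen after their values were seen, are Nek6, Selp, Cebpa, Tgfbi, Vim, Fn1, Col1a1, the other transcripts shown by replicate pair and the genes of the closing section.

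Same-numbered samples deviated together: the correlation of deviations from the group means was 0.635, 0.786 and 0.557 for pairs 1, 2 and 3, against -0.736 to 0.0712 for samples of different number. The numbers come from the labels and the harvests are described as independent in the series design, so the number is treated as pairing the samples, and the value with the replicate number as a block is given where it changes a call. The median residual SD was 0.241 without the block and 0.157 with it. Slides were told apart by the array files. Slide 1 held untreated replicates 1 and 3 and treated replicate 1, and slide 2 the others, so pairs 1 and 2 each lie on a single slide and pair 3 spans both.

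The gene test was run on simulated values with the means and spreads of the real genes and 200 changed genes. With the unpaired spread and no block, 24% of genes changed by a log2 value of 1 and 90% of those changed by 2 were called, and 0.038% of the unchanged genes. With pair effects and the block these were 72%, 98% and 0.0587%, and with pair effects and no block 0%, 64% and 0%. In a simulated list test with camera at the preset correlation, a list of 10 genes raised by 0.5 had an adjusted p of 1.12e-08. There 0 of the other lists were called. The simulated genes varied independently, whereas the estimated correlation on the real arrays reached 0.70, in the MYC and ribosome biogenesis list. The simulation therefore does not tell how often unchanged lists are called on the real arrays.

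The settings compared were normexp background correction (offset 50) with quantile normalization, quantile normalization, median centring, the authors' matrix values, other filters on dim probes, other ways to combine probes, slide and replicate blocks, each slide alone, an intensity trend, array weights, each array left out and other thresholds. Normexp was applied to the median spot signal, because the mean signal named in the plan is not among the columns used here. The array weights were 1.95, 0.37 and 1.10 for untreated replicates 1, 2 and 3. They were 0.40, 5.34 and 0.58 for treated replicates 1, 2 and 3. The weighted fit has no block, so it mainly sets treated replicate 2 (slide 2) against untreated replicates 1 and 3 (slide 1). Pair and slide differences therefore enter every value given with array weights. Replicates are independent harvests of one cell line. The gene p-values without a block measure change against the spread between harvests of these cells and do not use the pairing. Those with the replicate block measure it against the spread of the change between pairs. The block does not remove the slide difference from the change of pair 3, which spans both slides. Camera p-values at the preset correlation rest on the spread between genes, so they do not measure the spread between harvests.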

Results

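Gene expression was measured on 6 1-colour microarrays of RNA from Lhx2 cells, a mouse blood progenitor-like line that is kept growing in culture by enforced expression of the LIM-homeobox gene Lhx2 and depends on stem cell factor and interleukin 6. The cells were starved of serum overnight and then left untreated or given transforming growth factor β1 (TGF-β1) at 10 ng/ml for 2 h, with 3 arrays per group. The series title links TGF-β and Smad4 with Gata2 and p57 (Cdkn1c) in progenitor proliferation, and the comparison asks which transcripts 2 h of TGF-β1 raised or lowered. RNA came from 3 independent harvests, and an untreated and a treated sample with the same replicate number are called a pair here. The 75th percentile of the background-corrected signal lay between 794.2 and 1031 on the 6 arrays, and between 82.8% and 90.3% of probes were well above background. In exact permutation tests of both directions these measures did not separate the groups (p = 0.4 for the 75th percentile, p = 0.5 for the share of probes and p = 0.3 for the local background, where 0.1 is the smallest p that 3 against 3 arrays allow). These tests do not use the pairs. The local background was higher on the treated array of each pair (29.78 against 28.97, 28.91 against 25.19 and 28.5 against 26.04). A total of 29161 genes and transcripts were tested, 15633 of them with a gene symbol, and the number of arrays limits the precision of every value.

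TGF-β1 raised the transcripts of its own inhibitors within 2 h. Smad7, the inhibitory SMAD that binds the TGF-β receptor, rose 11.8-fold (log2 change 3.56, SE 0.15), Skil 11-fold (3.46, SE 0.13) and Ski 7.64-fold (2.93, SE 0.13), the last pair being transcriptional co-repressors of SMAD complexes. Ldlrad4, which encodes a membrane protein that restrains SMAD activation, rose 16.8-fold (4.07, SE 0.27), and Smad6, the inhibitory SMAD of the BMP branch, rose 6.79-fold (2.76, SE 0.16). The rise of greatest size among genes with a symbol was that of Kcne3, a potassium channel subunit, at 18.1-fold (4.18, SE 0.16). Hey1, a basic helix-loop-helix repressor known as a Notch and BMP target, rose 13.0-fold (3.70, SE 0.43), and Id3, an inhibitor of helix-loop-helix DNA binding, rose 10.5-fold (3.39, SE 0.34). Tmem119 rose 11-fold (3.46, SE 0.16) and Sec14l2 8.72-fold (3.12, SE 0.33). Among changed genes with a symbol, falls were fewer and smaller. St8sia4, a polysialyltransferase, was 3.33-fold lower (log2 change -1.74, SE 0.17), as was Pmaip1, which encodes the pro-apoptotic protein Noxa (-1.73, SE 0.16). Rgs18, a regulator of G-protein signalling in blood cells, was 3.05-fold lower (-1.61, SE 0.16), Calcrl 2.81-fold lower (-1.49, SE 0.18), the transcriptional repressor Gfi1 2.65-fold lower (-1.40, SE 0.14), the co-stimulatory receptor Cd28 2.56-fold lower (-1.36, SE 0.14) and thrombospondin 1 (Thbs1) 2.47-fold lower (-1.30, SE 0.16). The size depended on the background handling for Cd28, which had -0.44 with normexp (adjusted p = 0.0982) and -0.80 in the authors' matrix values, and for Hey1, which had 2.37 with normexp (0.0592).

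In all, 74 genes and transcripts changed at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, 66 of them higher and 8 lower after treatment (n = 3 per group). Of these, 49 had a gene symbol, 42 higher and 7 lower, so the named falls above are all of those with a symbol. Each of the 74 moved the same way in all 3 pairs and had groups that did not overlap, which 10.4% of all tested genes showed and 10% would by chance. The smallest change among them was 2.09-fold, that of Nek6 (log2 1.06). Adjusted p ranged from 0.000976 for Kcne3 to 0.044 for Calcrl among the genes named so far. Among the 25 transcripts without a symbol the changes ran from 19.3-fold higher to one that was at least 6.90-fold lower, not well above background on any treated array.

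**Figure D1:**
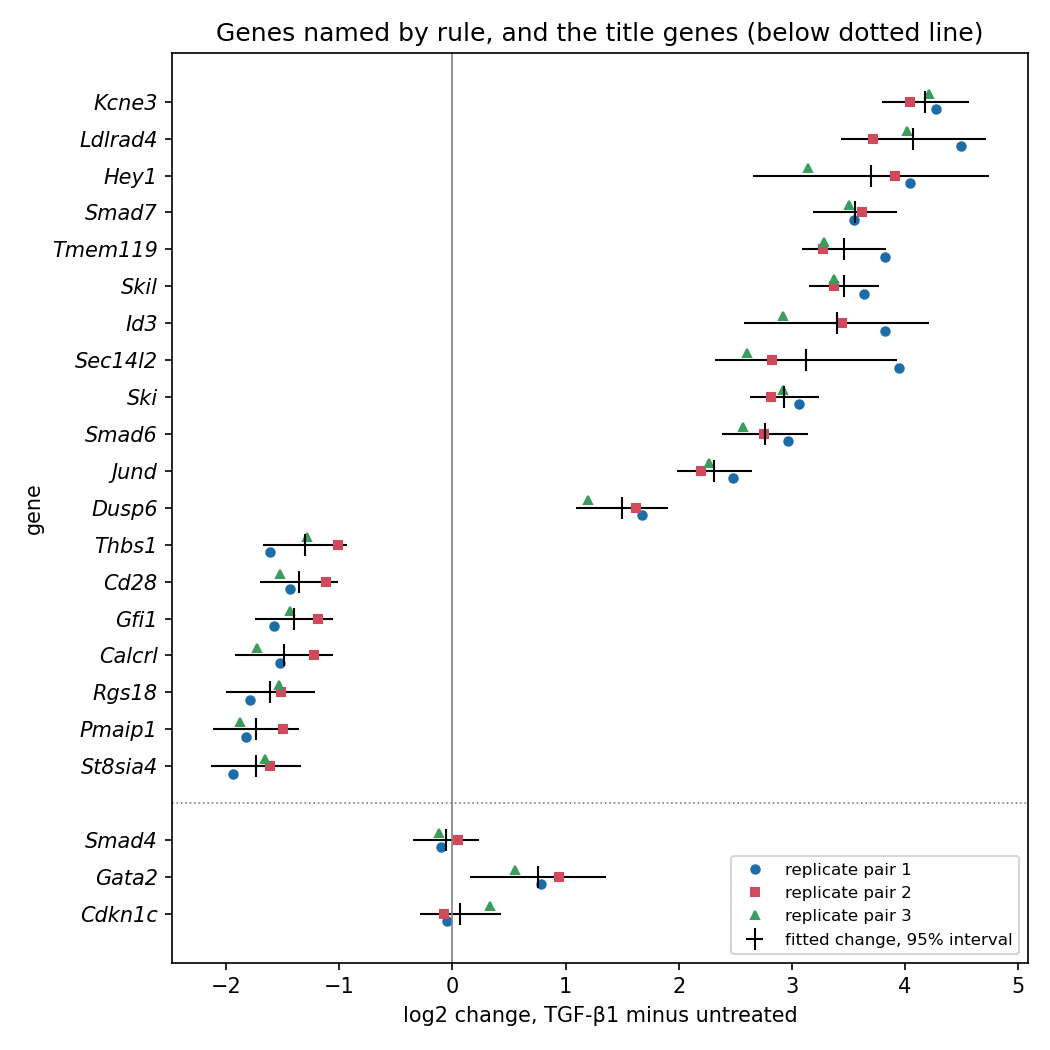
Log2 change (TGF-β1 minus untreated, horizontal axis) of the genes named by the rule, one per line, with Smad4, Gata2 and Cdkn1c below the dotted line. The vertical tick and bar are the fitted change and its 95% confidence interval over 3 arrays per group, and the coloured symbols are the 3 replicate pairs; the changed genes run from 4.18 for Kcne3 to -1.74 for St8sia4, while Smad4 (-0.06) and Cdkn1c (0.07) sit near 0.

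With the replicate number as a block the count was 196 (161 higher, 35 lower), including 73 of the 74, and the one that was lost was Thbs1 (blocked adjusted p = 0.0566). The arrays lay on 2 slides. With the slide as a block 59 genes changed, 50 of them among the 74. Hey1, Id3, Sec14l2, Calcrl, Cd28, Thbs1 and Dusp6 then had adjusted p between 0.0537 and 0.0857. Within slide 1 and within slide 2, 1 group has a single array, so only the size of change is given. The log2 changes of the 19 changed genes named by the rule were 0.939 to 1.25 of their main value within slide 1. Within slide 2 they were 0.794 to 1.11 of it. Pairs 1 and 2 each lie on a single slide; those 4 arrays alone, with the pair as a block, gave 67 genes (63 higher, 4 lower), a setting chosen after the data were seen. Leaving out any 1 array lowered the count to between 7 and 24.

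The list of TGF-β feedback and immediate target genes rose as a group. Of its 22 measured members 4 rose over all genes tested (Skil, Smad7, Ski and Ldlrad4) and 11 rose and 0 fell when adjusted over the list alone (12 and 1 with the replicate block). The median log2 change was 0.60 (camera adjusted p = 2.2e-18; adjusted p = 0.0364 with an estimated correlation). Klf10, a TGF-β-inducible zinc-finger gene, had 0.80 (SE 0.13, adjusted p = 0.0871). Pmepa1, another feedback inhibitor, had 1.79 (SE 0.28, adjusted p = 0.0836) and passed with the replicate block (adjusted p = 0.035). The list of ID genes and BMP-type targets also rose, with Smad6, Id3 and Hey1 past the threshold among 10 members, 6 higher and 0 lower when adjusted over the list alone, and a median of 0.94 (camera adjusted p = 1.6e-11; adjusted p = 0.0453 with an estimated correlation). Id1 had a log2 change of 1.14 (SE 0.19, adjusted p = 0.112) and Id2 of 0.91 (SE 0.14, adjusted p = 0.0788). These 2 lists had medians of 0.56 and 0.91 with the slide as a block, 0.57 and 1.06 within slide 1, and 0.35 and 0.65 within slide 2. With the replicate block and an estimated correlation together neither passed (adjusted p = 0.325 for both).

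TGF-β and BMP receptors and receptor SMADs had a median of 0.23 over 17 measured genes (camera adjusted p = 0.0143; adjusted p = 0.662 with an estimated correlation), and 0 members passed over all genes. Bmpr2, a type II BMP receptor, was the 1 that passed when adjusted over the list alone (log2 change 0.97, SE 0.15). Endoglin (Eng), a co-receptor of the family, had 0.92 (SE 0.26, adjusted p = 0.424) and passed over the list alone with the replicate block (0.00839), making 2 higher and 0 lower. The median of this list was 0.15 with the slide as a block, 0.32 within slide 1 and 0.07 within slide 2 (adjusted p = 0.17). The call rested on single arrays: the median was 0.05 without untreated replicate 3 (adjusted p = 0.154), 0.13 without treated replicate 1 (0.149) and 0.04 without treated replicate 2 (0.135).

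Of the genes in the title, none passed the threshold. Smad4, the common partner of the receptor SMADs, had a log2 change of -0.06 (SE 0.12, 95% confidence interval -0.35 to 0.23, adjusted p = 1), with a second probe at -0.04. Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, had 0.07 (SE 0.15, 95% confidence interval -0.29 to 0.43, adjusted p = 1), an interval whose upper end is 1.34-fold. Gata2, a zinc-finger transcription factor of stem and progenitor cells, had 0.76 (SE 0.25, 95% confidence interval 0.15 to 1.36, adjusted p = 0.626), or 1.69-fold. It was higher in every pair (0.78, 0.94 and 0.55), a second probe gave 0.77, and the standard error was 0.12 with the replicate block (adjusted p = 0.111 over all genes). Adjusted over its list of transcription factors alone, Gata2 had 0.0832 without the block and passed with it (0.0122). Within slides the Gata2 change was 1.05 on slide 1 and 0.62 on slide 2, and 0.84 with the slide as a block.

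Stem and progenitor transcription factors moved both ways, with 16 negative and 13 positive values and a test direction downwards. Their mean log2 change was -0.30. Gfi1 was the only one of 29 measured members to pass over all genes. Adjusted over the list alone, 5 fell and 1 rose (8 and 3 with the replicate block), and the median was -0.11 (camera adjusted p = 0.0226; adjusted p = 0.662 with an estimated correlation; 0.0524 with the replicate block). Mycn, a MYC-family transcription factor, was 14.9-fold lower in the fit (log2 change -3.90, SE 0.72, adjusted p = 0.144) with pair values of -4.93, -3.65 and -3.13. Meis1, a homeobox cofactor of self-renewal, had -1.41 (SE 0.22, adjusted p = 0.0871) and Cebpa, a driver of granulocytic differentiation, had -1.09 (SE 0.20, adjusted p = 0.147). Mycn (adjusted p = 0.038), Meis1 (0.0417) and Cebpa (0.0451) passed alongside Gfi1 when the replicate number was a block. The list's median was -0.10 with the slide as a block (adjusted p = 0.89), -0.10 within slide 1 and -0.13 within slide 2. The list did not pass without untreated replicate 1 (adjusted p = 0.24), treated replicate 2 (0.089) or treated replicate 3 (0.139), nor with normexp (median -0.03, 0.213), quantile normalization (0.0839) or the authors' matrix values (0.117). With array weights its median was -0.19 (0.00871).

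No list of cell-cycle regulators or phase genes passed in the comparison of all 6 arrays without block or weights. The 17 measured cyclin-dependent kinase inhibitors and antiproliferative genes had 0 members past the threshold over all genes or over the list alone and a median of 0.08, against a mean just below 0 (camera adjusted p = 0.526). Cdkn1a (p21) had a log2 change of 0.50 (SE 0.23, adjusted p = 0.933) and Cdkn1b (p27) 0.24 (SE 0.21, adjusted p = 1). The 25 G1/S genes had a median of -0.03 and a mean of 0.08, with a test direction upwards (camera adjusted p = 0.604). With the slide as a block the list passed upwards (median 0.07, adjusted p = 0.00715; within slide 1 0.04 and within slide 2 0.09, where it passed with 0.0143). With array weights it passed downwards (median -0.20, adjusted p = 0.0346), so its direction depended on the setting. Ccnd1, the gene of cyclin D1, had 0.78 (SE 0.33, adjusted p = 0.893) and was the 1 member that passed over the list alone with the replicate block (0.024). The 17 G2/M genes had a median of -0.09 (camera adjusted p = 0.21). Their list passed downwards with array weights (0.00124), without untreated replicate 2 (0.00389) and without treated replicate 3 (0.0319). All 20 measured genes of MYC and ribosome biogenesis had negative values, with 0 past the threshold over all genes or the list alone. The median was -0.16 (camera adjusted p = 0.00476; adjusted p = 0.887 with an estimated correlation). It was -0.03 with the slide as a block (adjusted p = 0.893), -0.04 within slide 1 and -0.05 within slide 2. With single arrays left out it ran from -0.06 without treated replicate 2 (adjusted p = 0.29) to -0.32 without untreated replicate 2, and it was -0.45 with array weights (5.88e-08). The call was also lost without untreated replicates 1 (0.286) and 3 (0.104) and treated replicate 3 (0.13). Myc itself had -0.57 (SE 0.22, adjusted p = 0.792).

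Sterol synthesis genes had a median of -0.28 over 11 members, 9 of them lower in all 3 pairs and 0 past the threshold over all genes or over the list alone (camera adjusted p = 0.0014; adjusted p = 0.67 with an estimated correlation). The median was -0.31 with the slide as a block, -0.42 within slide 1 and -0.19 within slide 2 (adjusted p = 0.27), and the call was lost without untreated replicate 3 (0.104). Over the list alone 1 member was lower with the replicate block.

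The remaining response lists did not pass. Apoptosis genes moved both ways: Pmaip1 fell, 4 of 25 rose and 2 fell when adjusted over the list alone (7 and 5 with the replicate block), and the median was -0.03 with a mean of 0.08 and a test direction upwards (camera adjusted p = 0.604). Bbc3, which encodes the pro-apoptotic protein Puma, had 1.23 (SE 0.16, adjusted p = 0.0502) and passed with the replicate block (adjusted p = 0.038). Of 22 immediate early genes, Jund rose 4.97-fold (log2 2.31, SE 0.14, adjusted p = 0.00397) and Dusp6, a phosphatase that switches off ERK, 2.82-fold (95% confidence interval 2.13 to 3.75, adjusted p = 0.0369), while Fos had 0.10 (SE 0.31) and Egr1 -0.24 (SE 0.40). Of the list, 2 rose and 1 fell when adjusted over the list alone (3 and 2 with the replicate block), and the list's median was 0.03 (camera adjusted p = 0.416). JAK-STAT and ERK feedback genes had 0 members past the threshold over all genes, 1 higher and 3 lower when adjusted over the list alone, and a median of 0.12 with a mean of -0.04 and a test direction downwards (camera adjusted p = 0.782). The kinases Pim1 (-1.02, SE 0.18) and Pim2 (-1.04, SE 0.23) of that list, which act in cytokine survival signalling, passed with the replicate block (adjusted p = 0.0423 for both). Haematopoietic cytokine receptors (15 genes, median 0.08, camera adjusted p = 0.666), interferon-stimulated genes (14 genes, median -0.16, camera adjusted p = 0.142) and heat shock and stress chaperones (11 genes, median -0.16, camera adjusted p = 0.0878) had 0 members past the threshold over all genes or over the list alone. Over the list alone 1 cytokine receptor was higher and 1 interferon-stimulated gene lower with the replicate block. The interferon list then passed downwards (adjusted p = 0.0416; adjusted p = 0.521 with an estimated correlation).

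**Figure D2:**
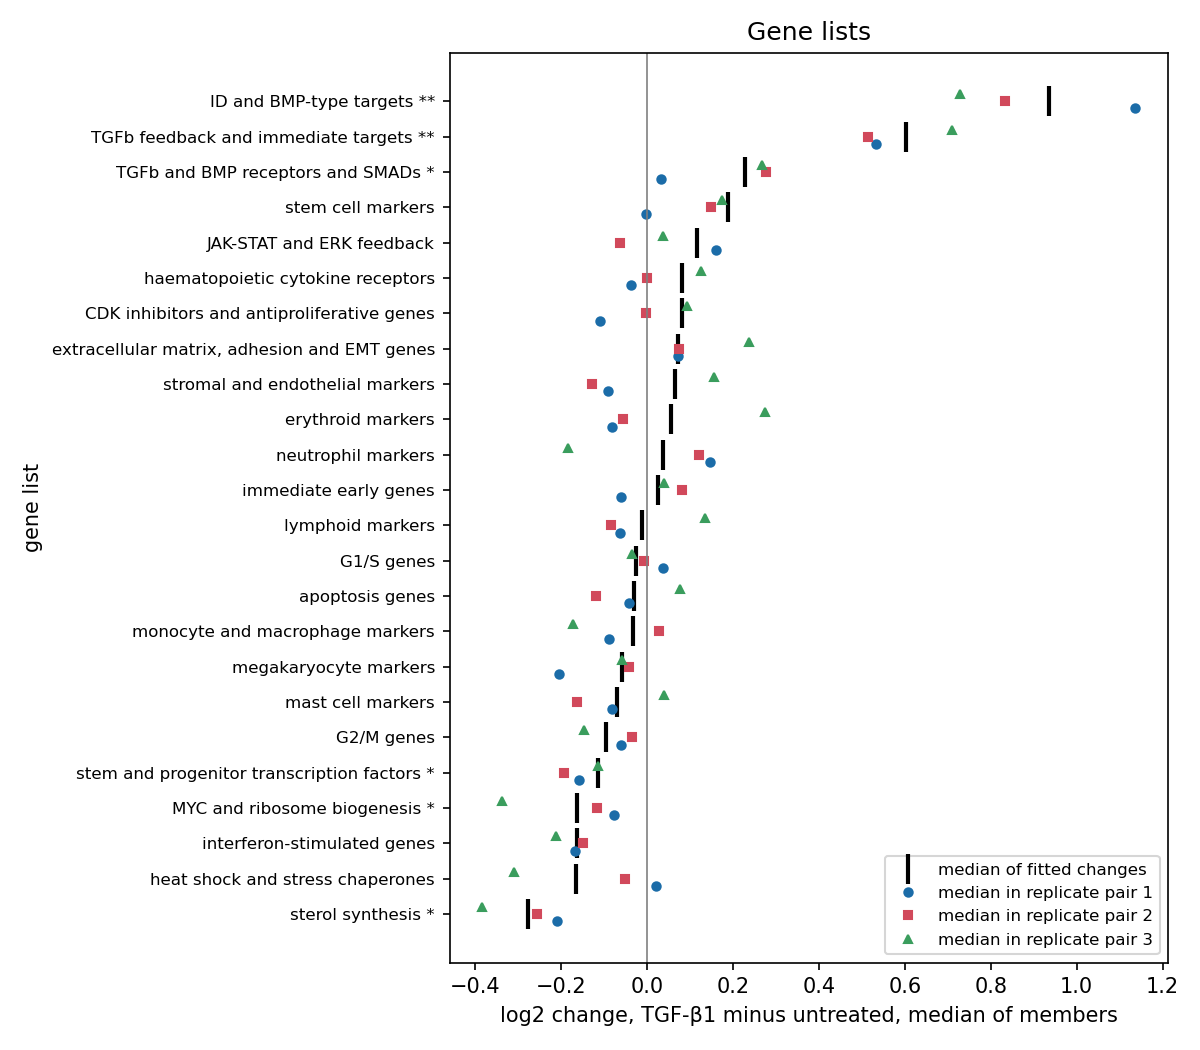
Median log2 change (TGF-β1 minus untreated, horizontal axis) of the measured members of each of the 24 gene lists. The black bar is the median of the fitted changes and the symbols are the medians in the 3 replicate pairs; a star marks lists past an adjusted p of 0.05 with the preset correlation and a double star those that also pass with an estimated correlation, which are the ID and BMP-type targets (median 0.94) and the TGF-β feedback genes (0.60).

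Extracellular matrix, adhesion and EMT genes, often raised by TGF-β in mesenchymal cells, had a median of 0.07 and a mean of -0.02 over 28 measured members, with a test direction downwards (camera adjusted p = 0.666), and Thbs1 was the 1 that passed, downwards, over all genes and over the list alone. The block by replicate number turned the only call over all genes into a rise. This was Tgfbi, a TGF-β-induced matrix protein (log2 change 1.04, adjusted p = 0.0414; 0.625 without the block). Over the list alone 3 members were then higher and 2 lower. The level of some members followed the replicate number, with 4 of the 28 over 3 log2 units lower in pair 3 than in both other pairs. The type I collagen gene Col1a1 was 12.1-fold higher in pair 1 and 56.5-fold higher in pair 2 than in pair 3, with a fitted treatment change of 0.04 (SE 1.87). Vim, which encodes vimentin, was only 1.01-fold and 1.42-fold higher, and Tgfbi was lower in pairs 1 and 2 than in pair 3. Within slide 1 the list's median was 0.34 and within slide 2 it was -0.57 (camera adjusted p = 0.0143), where the treated group includes the array of pair 3, and with the slide as a block -0.17.

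**Figure D3:**
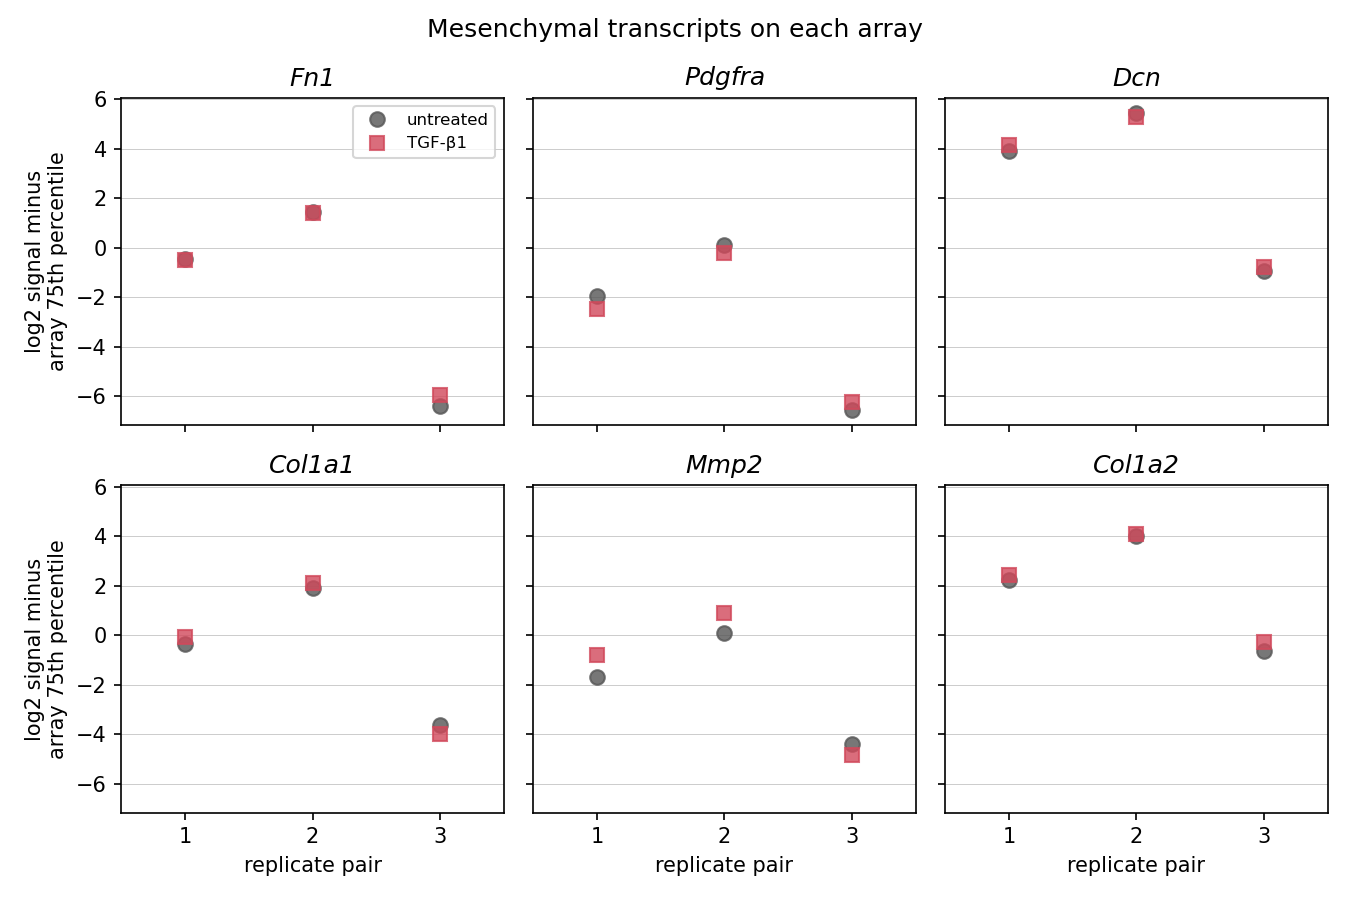
Log2 signal minus the array's 75th percentile (vertical axis) of Fn1, Pdgfra, Dcn, Col1a1, Mmp2 and Col1a2 on each of the 6 arrays, by replicate pair (horizontal axis), with circles for untreated and squares for TGF-β1-treated samples. Both arrays of pair 3 lie below those of pairs 1 and 2 in every panel, for Dcn at -0.87 on average against 4.04 and 5.38; Fn1 and Pdgfra were well above background on only 1 of the 2 arrays of pair 3.

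No marker of a blood cell type passed the threshold over all genes, and no marker list passed in the comparison of all 6 arrays. The brightest measured member of each list had a log2 change near 0: Mpo for neutrophils -0.02 (SE 0.12), Lyz2 for monocytes and macrophages -0.03 (SE 0.14), Srgn for mast cells -0.04 (SE 0.15), Pf4 for megakaryocytes -0.11 (SE 0.67), Tfrc for erythroid cells -0.19 (SE 0.18) and Cd79b for lymphoid cells -0.13 (SE 0.26), each with an adjusted p of 1. Cd34, the brightest stem cell marker, had 0.39 (SE 0.14, adjusted p = 0.675). The list medians were 0.19 for stem cell markers, -0.07 for mast cell, -0.06 for megakaryocyte, 0.06 for erythroid, 0.04 for neutrophil, -0.03 for monocyte and macrophage and -0.01 for lymphoid markers, with camera adjusted p of 0.144 for the stem cell markers and between 0.604 and 0.972 for the others. Median and test differ in sign for the neutrophil list, which the test places downwards (mean 0.03), and for the lymphoid list, which it places upwards (mean 0.06). The neutrophil markers were higher in pair 3 than in pairs 1 and 2 (by 1.45 and 0.62 in the median). The groups on each slide hold unequal shares of pair 3, so the within-slide medians of -0.64 on slide 1 and 0.25 on slide 2, where the list passed upwards (adjusted p = 0.0143), carry that difference. This list also passed upwards without untreated replicate 3 (adjusted p = 0.0425) and with the replicate block when both arrays of replicate 3 were left out (median 0.16, adjusted p = 0.0123), a setting chosen after the data were seen. Stem cell markers passed upwards without untreated replicate 1 (0.0293) and without treated replicate 3 (0.03). Both settings keep untreated replicate 2, on which the Procr probe read far below the other arrays. Without that array the stem cell list did not pass (median 0.23, camera adjusted p = 0.621). Without a block 1 marker passed when adjusted over its list alone, Selp, a megakaryocyte adhesion gene, with -1.27 (SE 0.27). With the block by replicate number Selp passed downwards over its list alone. So did 1 other megakaryocyte marker upwards and 1 monocyte and macrophage marker in each direction. The 10 stromal and endothelial markers had a median of 0.06 (camera adjusted p = 0.782). Decorin (Dcn), the brightest, had a change of 0.08 (SE 2.09), with a signal 30.1-fold and 76.0-fold higher in pairs 1 and 2 than in pair 3. Most of the list did not differ so: 3 of the 10 were over 3 log2 units lower in pair 3. The median differences of pair 3 from pairs 1 and 2 were -0.13 and -0.29.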

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

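Leaving out both arrays of a replicate number, alone or with the block, and leaving out genes low in pair 3 were chosen after the data were seen; the other settings were planned. The count of 74 changed genes was 187 with normexp and quantile normalization, 47 with median centring, 172 with the authors' matrix values, 170 with an intensity trend, 671 with array weights (475 higher, 196 lower) and 19 at an adjusted p under 0.01. It was 196 with the replicate block and 194 with that block without the genes low in pair 3. It was 0 within slide 1, 0 within slide 2 and 0 when both arrays of replicate 1, 2 or 3 were left out, fits with fewer arrays that call 0 of the 19 named changed genes. Single arrays left out gave 7, 24 and 17 (without untreated replicates 1, 2 and 3) and 15, 13 and 13 (without treated replicates 1, 2 and 3). The other settings stayed within 1.5 times, and 39 to 74 of the 74 genes were shared in the scaling, filter, probe, trend, weight and replicate block settings. The cause of the differences between scalings was not tested. No scaling moved the median of all genes by more than 0.0154. The fit with array weights mainly sets arrays of different pairs and slides against each other, so its count is not one of treatment changes alone.

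The 6 lists past the threshold became 2 with an estimated correlation, 2 with fry, 10 with array weights and 3 without both arrays of replicate 3, and lay between 3 (without treated replicate 2) and 9 (without untreated replicate 2) with single arrays left out. With the replicate block and an estimated correlation together 0 lists passed, a setting outside the 26 counted next. The TGF-β feedback and the ID and BMP-type lists passed, upwards, in each of those 26. The receptor list passed in 19, sterol synthesis in 20, MYC and ribosome biogenesis in 15 and the stem and progenitor factors in 12, with no change of direction. Of the lists that did not pass, heat shock genes passed downwards with array weights (0.0132), with every probe tested (0.0269) and without untreated replicate 2 (0.0104) or treated replicate 1 (0.0122). Interferon-stimulated genes did so with array weights (0.00364) and without untreated replicate 2 (0.00773) or treated replicate 1 (0.00537), and both lists without both arrays of replicate 1 or 2 (0.0342 to 0.0375). Matrix genes passed downwards without untreated replicate 3 (0.0491) and apoptosis genes upwards with every probe tested (0.0269). The replicate block changed no other list call than those given above.

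The 19 changed genes named by the rule gave 456 values under alternatives: 263 kept the call, 193 lost it and 0 changed direction. Their log2 change fell to as little as 0.324 of its value with normexp, 0.592 with the matrix values and 0.651 with the mean of a gene's probes. With single arrays left out it stayed between 0.89 and 1.11 of its value. Gata2 stayed positive and short of the threshold in all 25 alternatives (0.60 to 1.05; adjusted p 0.0744 to 1). Smad4 ranged from -0.12 to 0.02 and Cdkn1c from -0.06 to 0.15, with no call.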

Other observations

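The tests on slide and array scaling below were chosen after the result was seen; the other explanations had their tests written down before their outcome was known, although the patterns themselves were noticed in the same data.

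Further genes past the threshold, chosen here after their values were seen, fall outside the lists. The cytokine Il6 rose 2.63-fold (log2 1.40, SE 0.16, adjusted p = 0.037), the subunits of the enzyme that limits glutathione synthesis, Gclc and Gclm, rose 3.07-fold (1.62, SE 0.14, adjusted p = 0.0189) and 2.76-fold (1.46, SE 0.18, adjusted p = 0.0432), and Plk3, a stress-linked kinase, rose 4.58-fold (2.20, SE 0.21, adjusted p = 0.021). Each was higher in 3 of 3 pairs. With the replicate block the Notch ligand Jag1 (3.23, SE 0.70 without the block) had an adjusted p of 0.0282 and the Notch feedback gene Nrarp (1.38, SE 0.19) one of 0.028. The chemokine Ccl4 (-1.57, SE 0.25), the activation marker Cd69 (-1.30, SE 0.34) and the cytokine Il15 (-1.05, SE 0.15) were lower with the block, at 0.0476, 0.0311 and 0.0396.

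Hypotheses from these genes were tested on other list members, adjusted over 3 lists. Besides the genes named above, Osgin1 (1.09, SE 0.25; adjusted p = 0.0451 with the replicate block) was left out of the NRF2 list, and Hey1 and Hes1 (0.96, SE 0.25) out of the Notch list, because their rise had been seen. The 18 remaining NRF2 targets had a median of -0.063 (camera adjusted p = 0.298; 0.407 with an estimated correlation), which shows no rise of these other members as a group. The 11 remaining Notch targets had a median of -0.018 (adjusted p = 0.348; 0.407 estimated). The 15 NF-κB targets had a median of -0.218, with 8 of them lower and 2 (Bcl3 and Icam1) higher in all 3 pairs. The list did not pass (camera adjusted p = 0.0972, and 0.407 with an estimated correlation), which leaves a lower NF-κB output open.

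Some mesenchymal transcripts, such as Col1a1 and Dcn, differed between pairs far more than between treatments. In all, 88 genes and transcripts (68 with a symbol) were over 3 log2 units lower in pair 3 than in both other pairs, against 2 lower in pair 1 and 1 lower in pair 2. The slides do not account for this, since on slide 1 the added mesenchymal list had a median difference of -1.286 between untreated replicates 3 and 1, and on slide 2 one of -2.091 between treated replicates 3 and 2. Nor does scaling, since the median of all genes differed by 0.0405 while the list differed by -1.60. Cells of another type in the cultures of harvests 1 and 2 are a candidate source: of 27 mesenchymal genes listed before their values were looked at, 51.9% (14) were over 1 log2 unit lower in pair 3 in both arms, against 1.30% of all genes, a share between the bounds set beforehand for and against this source. Serpinh1 and Loxl1 of this list are also among the 88. Of the others, Thbs2 and Pcolce lay 2.75 and 2.75 log2 units lower in pair 3 than in pair 1, while Cxcl12 and Cdh11 did not (-0.17 and 0.29), and a change of state in the line itself stays open.

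Such cells could respond to TGF-β1 in their own right. Across the 88 genes low in pair 3, the changes of pairs 1 and 2, which share no array, correlated at 0.92 (genes are not independent replicates), against 0.628 across other genes above background on all arrays. Fstl1, Snai1, Tcim, Unc5b and Vasn rose by over 1 log2 unit in both pairs. Most of them were near background in pair 3, so their changes there do not tell whether such cells are the source, which stays a hypothesis.

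The main response was also seen in pair 3. For the 50 genes that moved most in pairs 1 and 2, the change in pair 3 was 0.912 of their mean (median ratio, quartiles 0.755 and 1.02). Of these, 46 had the same sign. The ratio alone cannot decide, since a transcript made only by such cells could keep its log2 change when they are fewer. Only 1 of the 50 was over 3 log2 units lower in pair 3. That mark cannot decide either, since most genes of the added mesenchymal list did not reach it. Whether mesenchymal cells contributed to the response as a whole is therefore not settled by these values. The 88 genes vary too much between harvests to be called without a block; with the replicate block 2 of them were called, Fstl1 (adjusted p = 0.0499) and Unc5b (0.0247).

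With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave 74 genes and the highest other 4353, so 2 splits gave as many; that other split is the slides, which points to a strong slide structure, and the values with the slide as a block and within slides are those given with the count. The remaining splits gave 0. For lists at the preset correlation, 6 splits, the real one included, gave at least the real 6, with 12 as the highest. A count of 6 lists is thus what other groupings of these arrays also give, and is not by itself a sign of treatment. Among the 4 splits that part every pair the highest other count was 3. The splits were compared by count and not list by list. With the replicate block, the 4 splits that part every pair gave 196 genes for the real one and 0 as the highest other (1 split as large), again too few for a share under 0.05.

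On untreated replicate 2, the Procr probe read 7.47 against 838.1 to 1869 on the other 5 arrays. It lifts the mean of the stem cell list to 0.34, which is 0.09 without it, while the median moves only from 0.19 to 0.18.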
